A study of Mus musculus with 9 samples.

How the data were processed

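Bulk RNA sequencing of microdissected atrioventricular (AV) nodes from C57BL/6J mice gave 9 libraries, 3 from control mice, 3 from Cx3cr1 Cx43-/- mice and 3 from macrophage-depleted Cd11bDTR mice. Per the labels' protocols, total RNA was treated with DNase and made into strand-directional libraries. The design text calls the 3 libraries of a group biological replicates, and it does not say whether nodes of several mice were pooled. Per the submitters' processing notes, STAR 2.3.0, HTSeq 0.6.0, edgeR and the mm9 build were used, in roles the notes do not give. The annotation behind the gene symbols is not given in the sources used here. Because the reference at hand was of another build, no coordinates are printed.

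The values deposited by the authors are CPM (counts scaled to a fixed total per library) rounded by them to 2 decimals, for 34198 gene symbols in 9 columns. Each column was matched to its sample by its name. Of the symbols, 12054 stood at 0 in all 9 libraries, and 0 began with the mitochondrial prefix mt-. The columns summed to between 28.3% and 48.7% of the total that CPM is scaled to, so the denominators held reads outside the listed genes. Low CPM values fell on multiples of the value of a single read, between 0.0154 and 0.0192 CPM. A gene at 1 CPM therefore rested on about 52.1 to 64.9 reads. After rounding, 21.3% to 44.9% of the low values lay within 0.1 read of a whole number. Reads were not rebuilt from the rounded values, and no count model was fitted. 0 pairs of libraries held identical values. Genes with many processed pseudogenes, such as Gapdh and Hspa8, can lose reads to their copies, and Gapdh stood at 2.59 ± 0.936 CPM (SD, n = 3) in control.

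The values were analysed as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3. A single linear model held all 9 libraries, with a trended empirical Bayes variance, and 3 contrasts were taken from it by two-sided tests. Genes entered with at least 1 CPM in at least 3 libraries, which left 12925. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of genes near the floor, and standard errors (SE) are those of the moderated fit. Mean CPM is given ± SD over 3 libraries. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so all p-values here are those of limma.

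Gene lists (42) were written before the data were examined, and 37 of them had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, and again with an estimated correlation. The fry test of limma, which asks whether a list's genes move on balance in a single direction, was an alternative. Counts of list members are given over all genes tested and adjusted over the list alone. The rule for naming genes was also fixed before the data were examined, and it picked most of them from these data by their values. Gja1, Cx3cr1, Itgam and Hbegf were named in every comparison whatever their result. Added to them were up to 10 called genes with the largest rise and 10 with the largest fall. These needed a mean of at least 5 CPM in a group, no overlap between the libraries of both groups, and a symbol of a characterised gene outside the ribosomal, immunoglobulin and T cell receptor families. For each called list, and for the lists of resident macrophages, connexins, conduction and both sets of ion channels in any case, up to 4 tested members with the smallest p were added, and a few of these are not reported here. Where the text names another gene, it says that this was done after its values were seen.

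Alternatives were pseudocounts of 0.1 and 2, no filter, a filter at a mean of 5 CPM, columns rescaled to a common total, quantile normalization, fits of only the 2 groups compared, library quality weights, robust empirical Bayes, other thresholds, and each library left out in turn. Median-of-ratios scaling was added after seeing the data. The fits were tested on simulated data of 12925 genes with 200 changed, in 10 draws per comparison. Noise was drawn independently per gene around a common mean, without a shift of whole libraries or groups. Changed genes were picked among those with a mean log2 value above 1. The rates below therefore do not cover low genes, noise shared between genes or a shift of all genes. For macrophage-depleted against control, 53.9% of genes changed by 1 on the log2 scale and 99.2% of those changed by 2 were recovered, with 5.20% false calls. For Cx3cr1 Cx43-/- against control these were 57.0%, 98.4% and 6.05%, and for macrophage-depleted against Cx3cr1 Cx43-/- they were 56.0%, 98.5% and 6.19%. Figures were drawn with matplotlib 3.10.9.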

Results

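Gene expression was measured in the AV node, the tissue that delays and relays the impulse from atria to ventricles, in 3 groups of 3 libraries. Control nodes were compared with nodes of Cx3cr1 Cx43-/- mice, in which the gap junction gene Gja1 (connexin 43) is deleted in Cx3cr1-expressing macrophages, and with nodes of Cd11bDTR mice depleted of macrophages through the diphtheria toxin receptor. Reads in listed genes took 45.6% ± 2.95 of the CPM denominator in control, 47.2% ± 0.625 in Cx3cr1 Cx43-/- and 36.7% ± 7.89 in macrophage-depleted libraries (SD, n = 3). The last group held 44.0%, 37.7% and 28.3% in libraries 7, 8 and 9. Symbols above 0 numbered 17294 ± 1911, 18096 ± 587 and 15606 ± 942 in the same order of groups. Control library 2 (15130 symbols) and depleted library 8 (14713 symbols) held the fewest in their groups.

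The first comparison asked what changed in the node when macrophages were depleted. Resident macrophage genes fell, with the scavenger receptor Cd163 at 0.217 ± 0.188 CPM against 13.2 ± 3.88 in control and the mannose receptor Mrc1 at 3.22 ± 0.944 against 40.3 ± 8.06 (SD, n = 3). Most listed inflammatory, acute phase and glucocorticoid-responsive genes rose, as did part of the cardiac stress genes. Large rises were those of the metallothionein Mt2 (572 ± 294 against 9.77 ± 2.25 CPM), osteopontin Spp1 (587 ± 76.4 against 14.0 ± 6.10) and lipocalin Lcn2 (98.0 ± 35.6 against 1.91 ± 0.705). On the deposited scale 17 of 24 conduction system genes fell, among them the calcium channel subunit Cacna2d2 (11.4 ± 3.66 against 91.2 ± 19.3 CPM). Of 20 cardiac potassium channel genes, 15 fell and 1 rose. Gja1 itself fell from 207 ± 41.8 to 71.7 ± 16.8 CPM.

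Of 12925 genes, limma called 4678, 417 higher and 4261 lower in the macrophage-depleted libraries, and 6055 had an unadjusted p under 0.05. On the deposited scale the median log2 change of all tested genes was -0.49, in the group with the lowest share of reads in listed genes. After rescaling each library to a common total over the listed genes, 1108 genes were higher and 2496 lower with a median of -0.19. Median-of-ratios scaling gave 1721 higher and 1655 lower, with a median of -0.03. The split between rise and fall therefore depended on the scaling. Without control library 1 the count was 2664, and 2632 of the 4678 calls were kept. At the preset correlation camera called 21 lists, and up to 19 in splits of the 6 libraries that mix the groups. List medians below are relative to the median of all genes. With an estimated correlation 0 lists were called on the deposited scale and 5 after rescaling to a common total, those of monocytes (adjusted p = 0.0307), conduction (0.0214), inflammatory (0.0214), acute phase (0.0308) and glucocorticoid-responsive genes (0.0297), and also 5 with median-of-ratios scaling.

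The genes named in every comparison came first. Gja1 stood at 89.9, 56.8 and 68.3 CPM in the depleted libraries, a log2 change of -1.53 (SE 0.22, limma adjusted p = 2.47e-05). In the second comparison, its deletion in Cx3cr1-expressing cells did not measurably lower Gja1 in the whole node. The fall of Gja1 here is therefore not shown to come from lost macrophages. Cx3cr1, the fractalkine receptor, stood at 2.07 ± 0.778 against 5.56 ± 1.75 CPM (-1.24, limma adjusted p = 0.0105), and the call was lost after rescaling to a common total (adjusted p = 0.0846) and with median-of-ratios scaling (adjusted p = 0.137). Itgam, which encodes CD11b, did not pass the test (6.47 ± 3.77 against 5.31 ± 3.65 CPM, log2 change 0.31, SE 0.44). Hbegf, the mouse homologue of the toxin receptor, rose from 12.7 ± 2.06 to 33.5 ± 18.2 CPM (1.24, limma adjusted p = 0.00245).

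Of 25 resident macrophage markers tested, 19 fell and 0 rose, and 20 fell when adjusted over the list alone. Their median was -1.35 (camera adjusted p = 4.01e-10, adjusted p = 0.22 with an estimated correlation). The complement gene C1qa (log2 change -2.53) and the growth factor receptor Csf1r (-2.74) were among them. The largest falls of all named genes included other genes of tissue macrophages, Retnla (0.290 ± 0.372 against 24.5 ± 5.56 CPM, -5.06), the lectin Mgl2 (-3.83), Fcrls (-3.70) and the folate receptor Folr2 (-3.67). Of 11 genes of MHC class II and dendritic cells, 7 fell, also 7 adjusted over the list alone, with a median of -1.27, or -0.74 without depleted library 8 (camera adjusted p = 0.000925, adjusted p = 0.403 with an estimated correlation). The invariant chain Cd74 stood at 18.8 ± 5.44 against 118 ± 41.7 CPM. All 5 tested mast cell markers fell, including the proteases Mcpt4 (-2.65) and Tpsb2 (-2.23), 5 also adjusted over the list alone (camera adjusted p = 0.00242, adjusted p = 0.335 with an estimated correlation). After rescaling to a common total 16 resident macrophage, 5 MHC class II and dendritic cell and 4 mast cell genes were lower. With median-of-ratios scaling these were 15, 5 and 4.

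Monocyte markers moved the other way. Of 9 tested, 6 rose and 0 fell, 6 also adjusted over the list alone, with a median of 1.59 (camera adjusted p = 4.95e-11, adjusted p = 0.0722 with an estimated correlation). Chi3l3 stood at 22.5 ± 8.80 CPM in the depleted libraries and 0.0167 ± 0.0153 in control, too close to 0 for a fold. Haptoglobin Hp (log2 change 2.64), fibronectin Fn1 (1.08) and Plac8 (2.24) rose as well, Hp with a wide spread (120 ± 125 CPM) and a call lost with robust empirical Bayes. On the monocyte list, Hp is also an acute phase list member and Nr4a1 an immediate early one. A rise of the list therefore need not come from monocytes. Hp stood at 58.9, 264 and 38.2 CPM in depleted libraries 7, 8 and 9, and the adipocyte genes Cfd (18.8, 175 and 31.6) and Cidec (2.97, 28.8 and 2.65), named after their values were seen, were also highest in library 8. In Cx3cr1 Cx43-/- library 4 Hp (2.50 CPM), Cfd (5.82) and Cidec (0.73) were the lowest of all 9.

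**Figure D1:**
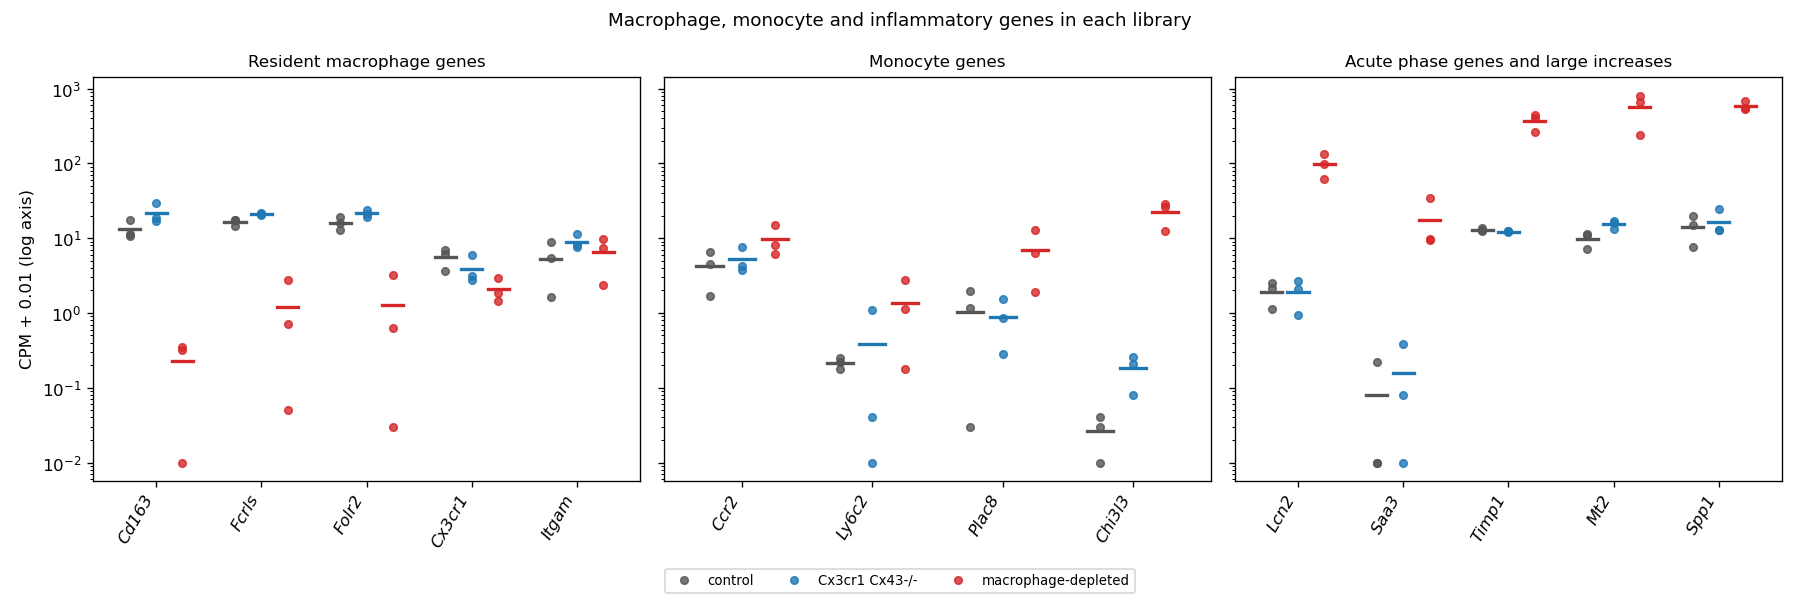
CPM + 0.01 on a log axis for resident macrophage genes (left), monocyte genes (middle) and acute phase and strongly raised genes (right), with a point per library (n = 3 per group) and a bar at the group mean. Cd163 lies at 0.217 CPM on average in the macrophage-depleted libraries and 13.2 in control, while Lcn2 lies at 98.0 and 1.91.

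Of 16 inflammatory cytokines and NF-kB targets tested, 12 rose, 12 also adjusted over the list alone, with a median of 2.19 (camera adjusted p = 6.65e-22, adjusted p = 0.0722 with an estimated correlation). The protease inhibitor Timp1 rose from 12.9 ± 0.623 to 367 ± 94.9 CPM (4.74, SE 0.22, limma adjusted p = 3.43e-13). The monocyte chemoattractants Ccl2 (3.32) and Ccl7 (3.20) and the cytokine signalling inhibitor Socs3 (2.45) rose too. Of 14 acute phase and STAT3 targets, 10 rose, 10 also adjusted over the list alone, with a median of 1.73 (camera adjusted p = 1.89e-23, adjusted p = 0.0722 with an estimated correlation). Serpina3n reached 566 ± 189 CPM against 15.3 ± 4.14, and Saa3 stood at 17.7 ± 14.1 against 0.0700 ± 0.121. Of 14 glucocorticoid-responsive genes, 11 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 1.74 (camera adjusted p = 1.01e-22, adjusted p = 0.0722 with an estimated correlation). They included Mt2, Mt1 (3.76), Lcn2 and the receptor co-chaperone Fkbp5 (2.37). Lists share members, so their calls are not independent. Of the glucocorticoid-responsive genes, Lcn2 is also on the acute phase list, Nfkbia on the inflammatory list and Dusp1 on the immediate early list. Pdk4 is also on the fatty acid list and Per1 on the clock list. Hp is on the monocyte and acute phase lists, and Nr4a1 on the monocyte and immediate early lists. The cardiac stress list shares Postn with the fibroblast list and Myh7 with the ventricular list. Further members are shared between other lists. Chi3l1 (4.70) and Serpina3m (6.36 ± 2.35 CPM against 0.0733 ± 0.127) completed the 10 largest rises.

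Cardiac stress and remodelling genes rose in 7 of 14 cases and fell in 1, or 8 and 2 adjusted over the list alone, with a median of 1.07 (camera adjusted p = 2.45e-12, adjusted p = 0.117 with an estimated correlation). The matricellular gene Ctgf rose from 159 ± 11.3 to 1501 ± 482 CPM (3.18), the natriuretic peptide gene Nppb by 1.69 and Ankrd1 by 1.55 on the log2 scale. Of 16 immediate early genes, 9 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 1.46 (camera adjusted p = 1.02e-11, adjusted p = 0.225 with an estimated correlation), among them Maff (2.41), Junb (1.71), Atf3 (1.80) and Fosb (2.01). Of 20 fibroblast and collagen matrix genes, 3 rose and 0 fell, 2 of them adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.000213, adjusted p = 0.225 with an estimated correlation). After rescaling to a common total 7 of them rose, and 11 with median-of-ratios scaling. The crosslinking enzyme Lox rose from 5.62 ± 0.148 to 51.1 ± 11.4 CPM (3.05), and Mfap5 by 1.08. Of 23 cell cycle genes, 3 rose, 2 adjusted over the list alone, including Birc5 (1.80), with a median of 1.18 (camera adjusted p = 9.21e-10, adjusted p = 0.117 with an estimated correlation), and 7 rose after rescaling and 12 with median-of-ratios scaling.

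Of 24 genes of the cardiac conduction system, 17 fell and 0 rose, and 19 fell adjusted over the list alone. The median was -0.84 (camera adjusted p = 7.09e-08, adjusted p = 0.225 with an estimated correlation). Besides Cacna2d2 (-2.97, SE 0.25, limma adjusted p = 6.97e-09), the T-type calcium channel genes Cacna1h (22.8 ± 5.95 against 127 ± 35.4 CPM, -2.45) and Cacna1g (24.5 ± 4.92 against 107 ± 7.78, -2.12) and Igfbp5 (58.8 ± 7.15 against 308 ± 71.2, -2.36) fell. Of 20 cardiac potassium channel genes, 15 fell and 1 rose, the same numbers adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.000213, adjusted p = 0.403 with an estimated correlation). The largest effects by p were those of the channel subunits Kcnip2 (-2.62) and Kcne1 (-2.23), Kcnh2 of the rapid delayed rectifier (-1.70) and the background channel Kcnk3 (-1.65). Rescaling to a common total left 15 conduction genes and 13 potassium channel genes lower.

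Of 9 connexins tested, 5 fell on the deposited scale and 0 rose, or 5 and 1 adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.442, adjusted p = 0.802 with an estimated correlation). Gja5 (connexin 40) fell by 1.86, Gja3 by 2.08 and Gjc1 (connexin 45) by 1.22 on the log2 scale beside Gja1. After rescaling to a common total 4 were lower and 1 higher, and with median-of-ratios scaling 4 and 2. Sodium and calcium channel genes did not stand apart either, with 5 of 14 lower, 5 also adjusted over the list alone, and a median of 0.02 (camera adjusted p = 0.424), or 3 lower and 1 higher with median-of-ratios scaling. The cation channel Trpm4 fell by 1.42, Scn10a by 1.89 and the sodium pump gene Atp1b1 by 0.83 on the log2 scale. Sarcomere genes had a median of -0.01 with 5 of 18 lower (camera adjusted p = 0.883), and atrial cardiomyocyte markers a median of 0.13 with 1 higher and 3 lower of 11 (camera adjusted p = 0.638). With median-of-ratios scaling these were 3 lower and 4 higher, and 1 and 1. Of 9 ventricular cardiomyocyte markers, 7 fell, 8 adjusted over the list alone, with a median of -0.68 (camera adjusted p = 0.00107, adjusted p = 0.225 with an estimated correlation), including the transcription factor Irx4 (-2.11), Gpr22 (-2.80) and Fhl2 (-1.41), and 4 fell with median-of-ratios scaling. The largest falls also held Myh7b (2.40 ± 0.723 against 40.5 ± 2.33 CPM, -3.85), Klhdc8a (-3.76), the dopamine receptor Drd2 (-3.63), the glucagon receptor Gcgr (-3.51) and Lingo3 (-3.51).

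**Figure D2:**
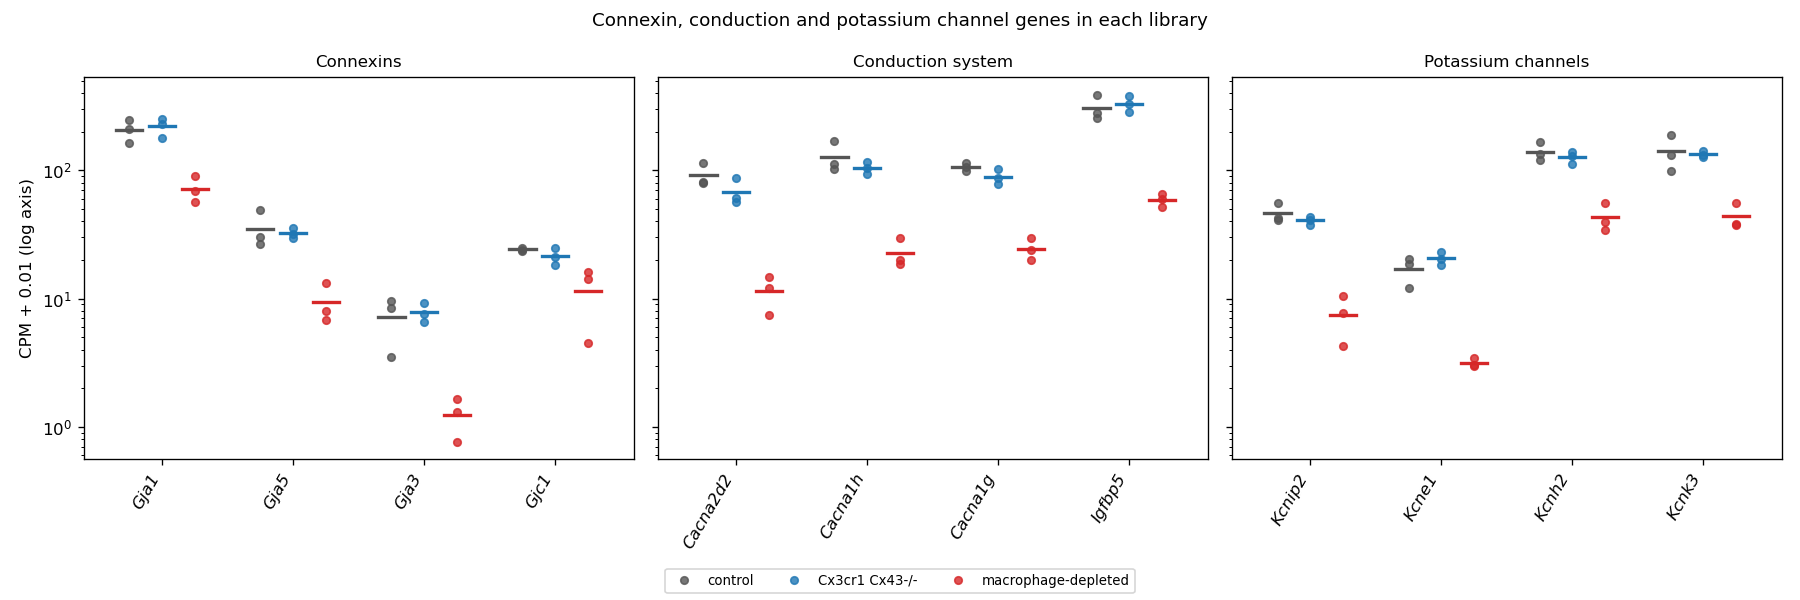
CPM + 0.01 on a log axis for 4 connexins (left), 4 conduction system genes (middle) and 4 potassium channel genes (right), with a point per library (n = 3 per group) and a bar at the group mean. Gja1 averages 207 CPM in control, 219 in Cx3cr1 Cx43-/- and 71.7 in macrophage-depleted libraries.

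Several lists were called with members going both ways. Of 16 clock genes, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone, with a median of 0.70, or 0.46 without depleted library 7 (camera adjusted p = 0.000676, adjusted p = 0.408 with an estimated correlation). After rescaling to a common total 6 rose and 2 fell, the same numbers as with median-of-ratios scaling. The repressors Gm129 (log2 change 3.60) and Per2 (20.1 ± 8.16 against 3.56 ± 1.46 CPM, 2.32) rose, and the activators Arntl (7.77 ± 4.18 against 24.3 ± 2.17 CPM, -1.71) and Npas2 (-1.70) fell. The labels give no time of day of collection for any group. Of 12 heat shock genes, 3 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.789 with an estimated correlation). The inducible Hspa1a (3.07) and Hspa1b (2.48), which are near-identical copies, rose with Hspb1 (1.54), while the constitutive Hspa8 fell (-3.24). Among 21 genes of fatty acid oxidation and PPAR targets, 2 rose and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.789 with an estimated correlation). The lipase inhibitor Angptl4 (3.19) and the pyruvate dehydrogenase kinase Pdk4 (2.10) rose, and the beta-oxidation enzymes Acadm (-0.90) and Hadha (-0.74) fell. The fatty acid list lost its call without each of control libraries 1 and 3 and depleted libraries 7, 8 and 9 and after rescaling to a common total (adjusted p = 0.0828), and had 7 higher and 1 lower with median-of-ratios scaling. The heat shock list lost its call without control library 1 or depleted library 7, after rescaling (adjusted p = 0.0744) and with median-of-ratios scaling (adjusted p = 0.0796), where 3 were higher and 1 lower. Both calls also ended without a filter and with quantile normalization, the heat shock call with a filter at a mean of 5 CPM, and the fatty acid call with quality weights or a pseudocount of 0.1.

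The remaining called lists had few called members. Of 20 interferon-stimulated genes 1 rose, Isg15 (0.82), and 2 fell, including Stat2 (-0.67), or 0 and 1 adjusted over the list alone (camera adjusted p = 0.00239, adjusted p = 0.403 with an estimated correlation). Of 13 adipocyte genes 2 rose, Plin4 (0.77) and Adig (1.47), and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00255, adjusted p = 0.564 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress response 1 rose, Atf4 (0.73), and 2 fell, Atf5 (-0.97) and Trib3 (-1.39), the same numbers adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.789 with an estimated correlation). Of 19 lysosome genes 2 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.789 with an estimated correlation). Cd63 rose by 0.79, and Lamp1 fell by 0.75 and Psap by 0.66 on the log2 scale. The balance of these counts turned with the scaling. After rescaling to a common total 5 interferon-stimulated genes were higher and 1 lower, 3 and 1 stress response genes and 8 and 2 lysosome genes, and with median-of-ratios scaling 7 and 0, 4 and 0, and 8 and 0. List calls were lost for interferon-stimulated genes without depleted library 9 (adjusted p = 0.169), adipocyte genes without depleted library 8 (0.192) and with median-of-ratios scaling (0.0585), stress response genes without control library 1 (0.0577) or depleted library 7 (0.163), and lysosome genes without control library 2 (0.0551) or depleted library 8 (0.0759). The adipocyte, stress response and lysosome calls also ended without a filter, and the interferon call with quality weights. Of the genes named in these last lists, Isg15, Stat2, Adig, Atf4, Atf5, Trib3, Lamp1 and Psap, and Hadha above, each lost its call in at least 1 fit without a library. After rescaling to a common total Stat2 and Trib3 lost theirs, and with median-of-ratios scaling so did Atf5, Lamp1, Psap, Hadha and Atp1b1.

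The second comparison asked what changed when Gja1 was deleted in Cx3cr1-expressing cells while macrophages stayed. A single gene passed the test. Cytl1, a secreted protein of cartilage, fell from 223 ± 24.3 CPM in control to 95.4 ± 17.7 in Cx3cr1 Cx43-/- libraries (SD, n = 3, log2 change -1.23, SE 0.20, limma adjusted p = 0.0330). Gja1 in the whole node was 219 ± 36.4 against 207 ± 41.8 CPM (0.09, SE 0.22), with 179, 229 and 250 CPM in the 3 libraries. Bulk RNA of the node thus did not show the deletion, and does not tell which cells made these reads. Cx3cr1 was 3.91 ± 1.71 against 5.56 ± 1.75 CPM (-0.48, SE 0.36) and Itgam 8.98 ± 2.08 against 5.31 ± 3.65 (0.93, SE 0.44), neither past the threshold.

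With limma, 191 genes had an unadjusted p under 0.05, where chance alone gives 646.2, 167 of them higher and 24 lower. The Cytl1 call was lost after rescaling to a common total (limma adjusted p = 0.0507), with a pseudocount of 0.1, without a filter, and without each of control libraries 2 and 3, Cx3cr1 Cx43-/- libraries 4 and 6 and depleted library 8. The median change of all genes was 0.07. Among members of the conduction list named by the smallest p, Cacna2d2 stood at 67.7 ± 16.2 against 91.2 ± 19.3 CPM and Shox2 at 12.1 ± 2.71 against 8.27 ± 1.56, and 0 of its 24 tested genes passed the test over all genes or adjusted over the list alone. None of 20 potassium channel, 14 sodium and calcium channel and 9 connexin genes passed either, with list medians of -0.01, 0.01 and 0.02.

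Camera called 20 of 37 lists in this comparison, 11 higher and 9 lower, with median shifts below 0.5 on the log2 scale. With an estimated correlation or with fry 0 were called. The camera calls thus rest on the preset correlation. Splits of the same libraries that mix the groups gave up to 17 camera calls. Such splits keep part of any group difference, so they do not measure how many calls chance gives. The resident macrophage list had a median of 0.32 (camera adjusted p = 6.09e-07, adjusted p = 0.409 with an estimated correlation), with 0 of 25 genes past the test, and Lyve1 stood at 27.8 ± 5.81 against 16.9 ± 6.53 CPM. The fibroblast and collagen list had a median of 0.28 (camera adjusted p = 9.44e-12, adjusted p = 0.125 with an estimated correlation). Col3a1 stood at 888 ± 85.9 against 521 ± 91.8 CPM and Fbn1 at 127 ± 17.6 against 77.6 ± 9.10, and 2 genes of the list passed adjusted over the list alone and 0 over all genes. The cell cycle list had a median of 0.48, or 0.30 without control library 2 (camera adjusted p = 1.46e-10, adjusted p = 0.173 with an estimated correlation), with Mki67 at 4.96 ± 0.263 against 1.96 ± 1.02 CPM. Interferon-stimulated genes had a median of 0.31 (camera adjusted p = 3.93e-08, adjusted p = 0.261 with an estimated correlation), with Irf7 at 16.9 ± 5.89 against 7.86 ± 2.70 CPM. The MHC class II and dendritic cell list had a median of -0.37, or -0.21 without control library 1, -0.70 without control library 2 and -0.58 without library 5 (camera adjusted p = 1.59e-07, adjusted p = 0.294 with an estimated correlation), with Cd74 at 75.4 ± 14.1 against 118 ± 41.7 CPM. The valve and cartilage list had a median of -0.26 (camera adjusted p = 0.000512, adjusted p = 0.125 with an estimated correlation), a call lost with library quality weights (adjusted p = 0.0778). Its members Comp (183 ± 6.90 against 279 ± 76.2 CPM) and Chad (85.9 ± 17.4 against 134 ± 44.2), beside Cytl1, did not pass the test. The conduction list had a median of -0.17 (camera adjusted p = 0.0117, adjusted p = 0.713 with an estimated correlation), or -0.11 without control library 2, and its call was lost without control library 1 (-0.21, adjusted p = 0.068) or library 6 (-0.10, adjusted p = 0.11). Among endothelial markers Vwf stood at 122 ± 20.8 against 49.2 ± 22.2 CPM (1.38, limma adjusted p = 0.401), past the test adjusted over the list alone.

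The third comparison set the manipulated groups against each other. In the macrophage-depleted libraries Gja1 was lower than in Cx3cr1 Cx43-/- libraries (71.7 ± 16.8 against 219 ± 36.4 CPM, log2 change -1.62, SE 0.22, limma adjusted p = 1.24e-05). Macrophage genes were lower, with Cd163 at 0.217 ± 0.188 against 21.6 ± 6.77 CPM and Mrc1 at 3.22 ± 0.944 against 58.0 ± 10.2. Lcn2 was higher (98.0 ± 35.6 against 1.88 ± 0.874 CPM, 5.38), as were Spp1 (5.16), Serpina3n (5.12), Timp1 (4.82) and the matrix protease Mmp3 (215 ± 86.4 against 13.8 ± 1.78 CPM, 3.85).

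Limma called 5604 genes, 348 higher and 5256 lower in the macrophage-depleted libraries, around a median change of all genes of -0.58. Rescaled to a common total there were 1077 higher and 2660 lower, with a median of -0.23, and with median-of-ratios scaling 1715 and 1635, with a median of -0.05. Without Cx3cr1 Cx43-/- library 5 the count was 3302, and 3300 of the 5604 calls were kept. Of 24 conduction genes 20 were lower, 20 also adjusted over the list alone, with a median of -0.74 (camera adjusted p = 1.07e-06, adjusted p = 0.348 with an estimated correlation), including Igfbp5 (-2.48), Cacna1h (-2.19) and the cell adhesion gene Cntn2 (37.4 ± 7.03 against 140 ± 15.6 CPM, -1.90), and 14 were lower after rescaling and 11 with median-of-ratios scaling. Of 20 potassium channel genes 16 were lower and 1 higher, the same numbers adjusted over the list alone, with a median of -0.87 (camera adjusted p = 0.000101, adjusted p = 0.431 with an estimated correlation), including Kcne1 (-2.53) and Kcnj11 (-1.64). Of 25 resident macrophage markers 20 were lower, 21 adjusted over the list alone (camera adjusted p = 6.49e-13, adjusted p = 0.135 with an estimated correlation). Monocyte markers had a median of 1.60, with 5 higher and 1 lower of 9, the same numbers adjusted over the list alone (camera adjusted p = 1.46e-12, adjusted p = 0.0645 with an estimated correlation). Inflammatory and NF-kB genes had a median of 1.84, with 8 of 16 higher, 8 also adjusted over the list alone (camera adjusted p = 8e-20, adjusted p = 0.0645 with an estimated correlation), or 12 after rescaling and 13 with median-of-ratios scaling. Of 9 connexins 6 were lower, 6 also adjusted over the list alone, Gja5 by -1.78 and Gja3 by -2.28 (camera adjusted p = 0.473, adjusted p = 0.791 with an estimated correlation). After rescaling 3 connexins were lower, and with median-of-ratios scaling 3 and 1 higher. Of 14 sodium and calcium channel genes 7 were lower and 0 higher, or 8 and 1 adjusted over the list alone, with a list median of -0.01 (camera adjusted p = 0.383), while 5 were lower and 2 higher after rescaling, and 3 and 2 with median-of-ratios scaling. Camera called 16 lists, 11 higher and 5 lower, and up to 23 in splits of these libraries that mix the groups. With an estimated correlation camera called 0 on the deposited scale, 5 after rescaling and 5 with median-of-ratios scaling, the conduction list among them (adjusted p = 0.0251 and 0.0223).

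**Figure D3:**
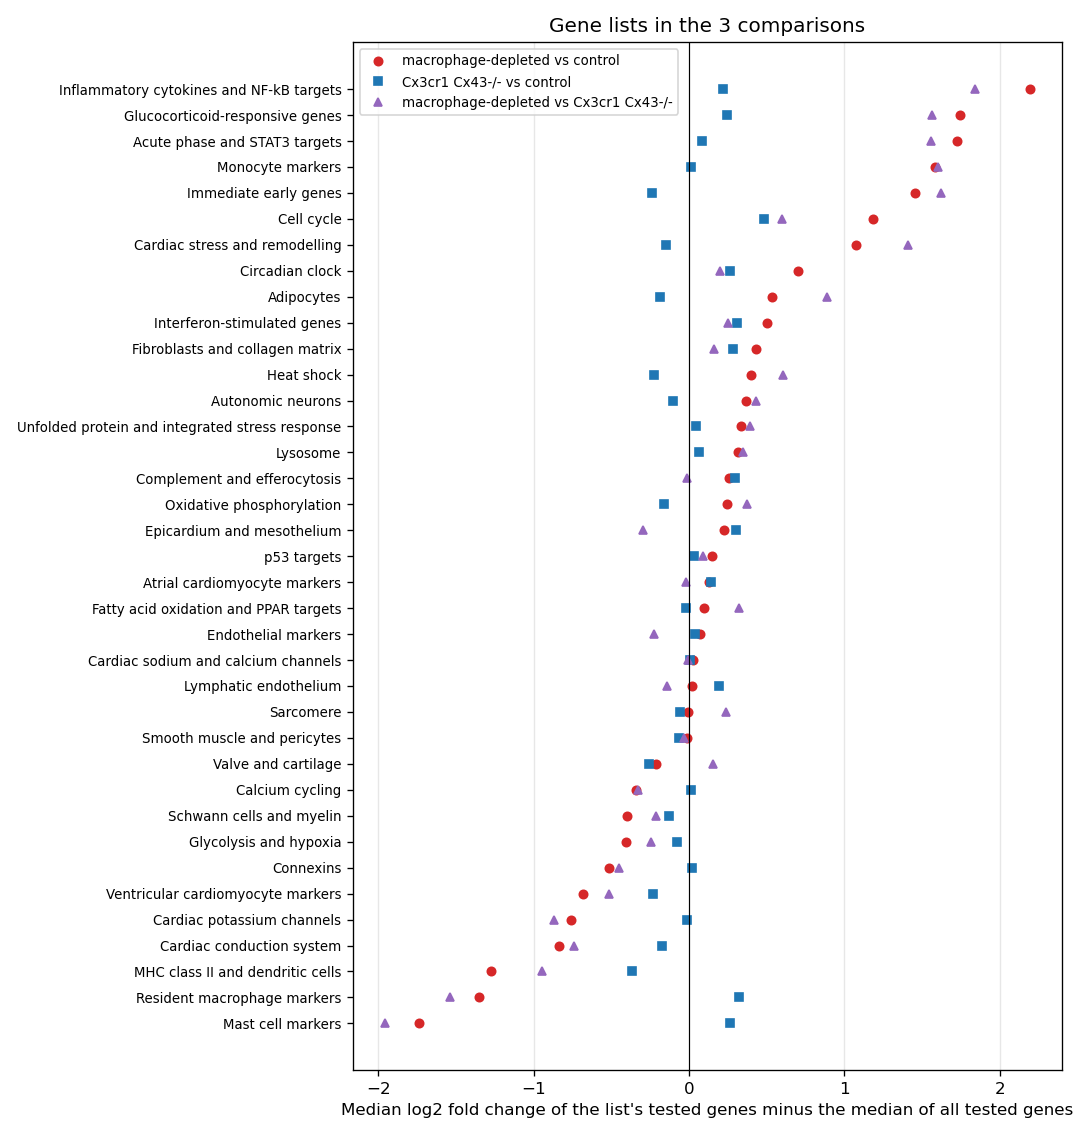
Median log2 change of each list's tested genes minus the median of all tested genes (horizontal axis) for the 37 lists tested, ordered by macrophage-depleted against control (circles), with Cx3cr1 Cx43-/- against control (squares) and macrophage-depleted against Cx3cr1 Cx43-/- (triangles). In the first, medians run from -1.74 for mast cell markers to 2.19 for inflammatory and NF-kB genes, while those of Cx3cr1 Cx43-/- against control stay between -0.37 and 0.48.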

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

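Only median-of-ratios scaling was chosen after seeing the data. Against control, the macrophage-depleted count (4678 reported) ran from 2664 (without control library 1) to 6274 (without depleted library 7) as libraries were left out, and was 2373 with an absolute log2 change over 1, a stricter rule. For Cx3cr1 Cx43-/- (1 reported) it ran from 0 to 2, and was 0 with a pseudocount of 0.1, without a filter or rescaled to a common total, 2 with a pseudocount of 2 and 4 with quality weights. Between the manipulated groups (5604) it ran from 3302 to 7049, and was 3356 with quantile normalization, 3350 with median-of-ratios scaling and 2797 with the fold limit. Apart from the stricter rule, the cause was not tested. On the deposited scale all 21, 20 and 16 list calls ended with an estimated correlation (0, 0 and 0 lists), while 5, 0 and 5 lists were called with it after rescaling to a common total and 5, 0 and 5 with median-of-ratios scaling. Fry called 20, 0 and 21. Fry, which does not compare a list with other genes, gave the opposite direction, past no threshold, for lists whose own median lay between -0.39 and 0.02, above the median of all genes: interferon-stimulated (relative median 0.50), heat shock (0.40), unfolded protein (0.33), fatty acid oxidation (0.097) and lysosome (0.32) genes in the first comparison, and unfolded protein (0.39), cell cycle (0.60) and clock (0.20) genes in the third. Of the list medians given, those of the first comparison moved by over 1.5 times with a pseudocount of 2 (inflammatory 1.28, MHC class II -0.56, mast cell -1.03, fatty acid 0.15), without a filter (1.26, -0.73, -0.86 and -0.19, clock 0.42, fibroblast 0.14, interferon 0.21, heat shock 0.11, unfolded protein 0.05, lysosome 0.01), with quantile normalization (fibroblast 0.24, heat shock 0.25, fatty acid -0.04, lysosome 0.16), with quality weights (interferon 0.31, unfolded protein 0.52, fatty acid 0.28), with the filter at 5 CPM (fatty acid 0.18), and without depleted library 7 (heat shock 0.24), 8 (unfolded protein 0.21, lysosome 0.20) or 9 (interferon 0.17, fatty acid 0.26) or control library 2 (fatty acid 0.29). For Cx3cr1 Cx43-/- they moved with a pseudocount of 2 (cell cycle 0.25), without a filter (valve and cartilage -0.15) and with quality weights (MHC class II -0.63, conduction -0.10). In the third they moved with a pseudocount of 2 (inflammatory 1.21, clock 0.11), without a filter (inflammatory 1.13, unfolded protein 0.07, cell cycle 0.30, clock -0.12), with quantile normalization (unfolded protein 0.19), at 5 CPM (clock 0.08), and without library 4 (clock 0.11), 5 (clock 0.31), 8 (clock 0.08) or 9 (clock 0.48, cell cycle 0.33). List calls of the first comparison ended without a filter (adjusted p: adipocyte 0.0573, heat shock 0.224, unfolded protein 0.181, fatty acid 0.497, lysosome 0.288), at 5 CPM (heat shock 0.139), quantile normalization (heat shock 0.247, fatty acid 0.662), quality weights (interferon 0.0586, fatty acid 0.109) or a pseudocount of 0.1 (fatty acid 0.057). In the third the clock call ended without a filter (0.242), at 5 CPM (0.0867), quantile normalization (0.091) and without library 4 (0.0815) or 7 (0.0898), the unfolded protein call without a filter (0.216), with quantile normalization (0.055) and without library 6 (0.0636) or 7 (0.165), and the cell cycle call without library 9 (0.0773). Of the genes named for the first comparison, Cx3cr1, Gjc1, Plac8, Hadha, Isg15, Adig, Atf4, Atf5, Trib3, Lamp1 and Psap lost their calls without a filter, Cx3cr1, Atf5, Stat2 and Trib3 with quantile normalization, Isg15, Psap and Stat2 with only the 2 groups, and Adig with a pseudocount of 0.1. For Cx3cr1 Cx43-/-, the atrial list median ran from -0.058 without control library 2 to 0.29 and the adipocyte median from -0.65 to 0.12 without library 4, and both calls also ended without a filter, with only the 2 groups and with quality weights. With a library left out, 13 of 99, 1 of 1 and 5 of 79 called named genes lost their call at least once. So did 6 of 21, 11 of 20 and 3 of 16 lists. The 99 and 79, mostly picked by size or p, understate the loss among all calls. The planned edgeR and DESeq2 fits were not run, as reads were not rebuilt from rounded values. Rounding alone did not bar this for low values (100% on multiples of a single read in every library). No pairing was possible, as groups share no replicate number.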

Other observations

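The tests of the CPM denominator, the cardiomyocyte share and neutrophils were chosen after the result was seen, and those of genomic DNA, transcript length and GC, and other splits before. Lists with under 5 tested genes were not tested as lists. Of the neutrophil list, which also holds Lcn2, Ly6g, Mpo and Elane were listed at 0 in all 9 libraries. S100a8 stood at 3.31, 1.63 and 0 CPM in the depleted libraries and 0.13, 0 and 0 in control, S100a9 at 1.43, 1.52 and 0.28 against 0.02, 0 and 0, Cxcr2 at 0.38, 0.4 and 0.35 against 0.03, 0 and 0, and Mmp8 at 0.66, 0.69 and 0 against 0 in each. Mmp9 fell from 3.85 ± 1.23 to 0.427 ± 0.416 CPM (SD, n = 3, limma adjusted p = 0.000460), named after its value was seen, as are all genes of this paragraph. Of the B cell genes, Ighm fell from 7.81 ± 2.64 to 0.557 ± 0.684 CPM in the depleted libraries (limma adjusted p = 3.14e-05) and Blk from 2.52 ± 0.402 to 0.660 ± 0.632 (limma adjusted p = 0.00707). Hemoglobin Hbb-b1 stood at 16.4 ± 5.50 CPM in Cx3cr1 Cx43-/- and 5.39 ± 3.24 in control libraries, past no threshold (limma adjusted p = 0.702).

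The clock genes of this paragraph were also named after their values were seen. In macrophage-depleted against control libraries Dbp stood at 16.6 ± 10.2 against 10.3 ± 2.59 CPM, Nr1d1 at 99.8 ± 65.0 against 62.7 ± 12.5 and Tef at 62.6 ± 22.7 against 44.5 ± 5.37, none past the test on the deposited scale, while after rescaling to a common total Tef (limma adjusted p = 0.00281) and Nr1d1 (0.0176) passed. Hlf fell by 0.86 on the log2 scale (limma adjusted p = 0.0394), a call lost after rescaling (0.127) and in 6 of the 9 fits without a library, and Per1 rose by 1.38 (limma adjusted p = 0.00553). In Cx3cr1 Cx43-/- libraries Dbp stood at 21.8 ± 6.04 CPM.

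On the deposited scale most called genes were lower in the macrophage-depleted libraries, while with quantile normalization 53.4% were and with median-of-ratios scaling 49.0%. Genomic DNA is opposed by olfactory and vomeronasal receptor genes, silent in heart, which summed to 10.2 ± 2.77 CPM there and 13.4 ± 4.15 in control, a ratio of 0.757. Reads outside the listed genes account for part of the shift, which went from -0.49 to -0.19 after rescaling to a common total, and between -0.23 and -0.15 without any single library, so they are not the whole of it. The 10 highest genes held 10.2%, 9.30% and 10.2% of the reads in listed genes in depleted libraries 7, 8 and 9. In control libraries 1, 2 and 3 they held 10.9%, 11.2% and 11.1%. These shares, compared after the result was seen, argue against a larger share taken by the 10 highest genes. Raised genes beyond these and the loss of cells remain open, and a biological difference between the groups is untested here.

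Conduction and potassium channel genes were lower in the macrophage-depleted libraries. A lower share of cardiomyocytes as a whole is opposed by the mean log2 level of the 44 genes of both lists minus that of the sarcomere genes, which was -6.76 ± 0.0674 in depleted and -5.91 ± 0.261 in control libraries, a change of -0.86. Length and GC bias is opposed by a median of -0.67 after its trend was removed, against -0.81 before. A smaller amount of nodal or of ventricular tissue in the dissection stays open, the latter because ventricular markers fell by about as much (7 of 9 lower, median -0.68, camera adjusted p = 0.00107). A response of cardiomyocytes to depletion, to the inflammation beside it or to toxin may underlie the change, and which mice received toxin is not given in the labels.

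Acute phase and NF-kB target genes were higher in the macrophage-depleted libraries. Neutrophils as the source of Lcn2 are opposed by S100a8 plus S100a9, abundant in these cells, at no more than 0.0357 of Lcn2 in any depleted library. Whether recruited monocytes, dying cells or resident stromal cells made the acute phase transcripts stays open.

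With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.05. For called genes, 1 split, the real one, gave as many in each comparison: 4678, 1 and 5604 genes for macrophage-depleted against control, Cx3cr1 Cx43-/- against control and macrophage-depleted against Cx3cr1 Cx43-/-, with at most 0, 0 and 0 in the others. For called lists, the real splits gave 21, 20 and 16 and the highest others 19, 17 and 23, and 1, 1 and 4 splits gave as many. Camera at the preset correlation thus called many lists in some splits that mix the groups. Each such split has unequal numbers of both groups on a side, so it keeps part of the group difference. The rest of that difference adds to the spread within each side. Neither the lists nor the 0 genes called in mixed splits therefore measure what chance gives, and these splits leave the list calls undecided.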
